A study of Mus musculus with 6 samples.

How the data were processed

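RNA from purified mouse erythroid progenitor cells was profiled at 3 stages, 80, 100 and 120 h after thiamphenicol withdrawal, with 2 arrays per stage. Per the labels, total RNA was converted to labelled cRNA and hybridised to Affymetrix murine genome U74 version 2 arrays of set A as the maker recommends. The deposited values are 1 linear intensity per probe set and array, from 0.3 to 173560. Every array had the same trimmed mean within 0.0337%, which shows from the values that the deposited intensities had been scaled to a common level. The software that summarised the probes is not given in the sources used here. Detection calls were not used here.

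The table held 12488 probe sets. GEO's platform annotation paired 10855 of them with 1 gene symbol, 396 with several and left 1237 unlisted. Genes were named only from probe sets with 1 symbol, of which 10839 were found by gene identifier in the RefSeq gene table and none needed a new symbol. The 66 control probe sets were left out of the tests.

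Each array was scaled to the same mean after trimming 2% of values at each end, which changed almost nothing. An offset of 104.8, the 25th percentile of all values, was added before taking log2, so fold changes of dim probe sets are understated and their ranks depend on it. Probe sets above 379, the 50th percentile of all values, on at least 2 of the 6 arrays were tested, 7150 in number. They named 5401 genes, each represented by its brightest tested probe set. The stages were compared with limma 3.58.1 in R 4.3.3, with 1 mean per stage, all 6 arrays in 1 fit, 3 residual degrees of freedom and a variance prior that follows the signal. The comparisons were 100 h with 80 h, 120 h with 100 h, 120 h with 80 h, all 3 stages together, and 100 h with the mean of the others. P-values are two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05.

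The design, the alternatives, the 31 gene lists and the rule for naming genes were set before the data were examined. Lists were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes, and adjusted over the lists. Of the 31 lists none passed with a correlation estimated from these arrays, and 8, 8 and 6 did so before adjustment in the 3 comparisons of stage pairs. The estimated-correlation p is therefore printed beside each called list. The estimate differed between lists, at 0.25 for red cell membrane genes but -0.02 for glycolysis and -0.03 for macrophage markers. Lists with an estimate below the preset value also lost their call, so a high correlation is not the reason for those. A list of mitochondrial ribosomal proteins, added later, had an estimate of 0.01, equal to the preset value. At 100 h against 80 h its camera adjusted p was 6.8e-14 with the preset and 0.0096 with the estimate. The 2 settings thus differ by more than the correlation, and a high estimated-correlation p is not by itself evidence of correlated genes. The limma function fry was an alternative.

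Genes were named by this rule. For each pair of stages, the 10 highest and 10 lowest log2 fold changes were taken among genes that passed the test and whose replicates did not overlap between stages. Kit, Epor, Gata1, Gata2, Klf1, Tfrc, Slc4a1, Alas2, Car1, Car2, Myc, Myb, Cish, Bcl2l1 and Pim1 were added wherever measured, and 1 further gene of this part is not reported here. Up to 4 members with the largest change were added per list, and the 5 largest turns at 100 h in each direction. Tmem14c, Irf1, Csf3r, Lcn2 and Shc1 in the results were singled out after their values were seen.

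The fit was tested on simulated data for 120 h against 80 h, with 200 of 7150 probe sets changed in each of 20 runs. In the first version the residual SDs were shuffled among probe sets, and limma recovered 28.8% of 2-fold and 75.6% of 4-fold changes with 5.05% of calls false. Shuffling breaks the link between signal and spread, so a second version gave each probe set its own SD as moderated by limma. It was written after the first result was seen. The first version used SDs without moderation, so the difference between the versions cannot be assigned to the shuffling alone. It recovered 56.0% of 2-fold and 96.0% of 4-fold changes with 6.35% of calls false, slightly above the threshold. No call in either version had the wrong sign. In the data many more probe sets were called at 120 h against 80 h, 2672 of 7150. The simulated shares may therefore not hold for these data.

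Alternatives were quantile normalization, median scaling, no scaling, other offsets, a floor, other filters, a replicate block, other variance models, averaging the probe sets of a gene, leaving out probe sets shared by gene families, and leaving out each array in turn.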

Results

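The data set holds RNA profiles of mouse erythroid progenitor cells, the spleen cells that mature into red blood cells, on Affymetrix murine genome U74 version 2 arrays of set A. Thiamphenicol is an antibiotic that holds back erythroid maturation, and its withdrawal lets a wave of progenitors mature together. Cells were purified with magnetic beads 80, 100 and 120 h after withdrawal. The labels call these stages I, II and III. They describe them by surface proteins and light scatter. The 80 h cells carried abundant Kit and Epo receptor and no Ter119. The 100 h cells carried little Kit, abundant Epo receptor and Ter119. The 120 h cells carried no Kit, less Epo receptor and abundant Ter119. Each stage has 2 arrays, which the labels call replicate hybridizations, so the p-values measure only the spread between these arrays, which may be technical. The 6 arrays limit the precision. A level is given as mean signal ± SD (n = 2), and a log2 fold change, taken on log2(signal + 104.8), with its SE from limma.

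Replicates resembled each other more than arrays of different stages did. Over the 7150 probe sets tested, Pearson's r across probe sets, which are not independent replicates, was 0.949 to 0.962 between replicates, 0.668 to 0.680 between the 80 h and 100 h arrays, 0.794 to 0.811 between 80 h and 120 h, and 0.893 to 0.908 between 100 h and 120 h. The first principal component held 73.0% of the variance and placed the 120 h arrays (-10.1 and -14.0) between those of 80 h (54.8 and 56.5) and those of 100 h (-43.4 and -43.7). On the second, with 11.4%, the 120 h arrays (-22.8 and -22.3) lay apart from those of 80 h (6.69 and 7.63) and 100 h (17.3 and 13.5). In limma's moderated F test, 3599 probe sets differed between stages at an adjusted p threshold of 0.05, against 1750 without moderation.

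The transcripts of the surface proteins in the labels were examined first. Kit, the stem cell factor receptor, gave 986 ± 302 at 80 h, 310 ± 21.1 at 100 h and 710 ± 236 at 120 h. It was lower at 100 h than at 80 h (log2 fold change -1.37 ± 0.30, limma adjusted p = 0.0063), while 120 h did not pass the test against 100 h (0.95 ± 0.30, adjusted p = 0.08) or against 80 h (-0.42 ± 0.30, adjusted p = 0.3). The labels describe the 120 h cells as without surface Kit. Epor, the erythropoietin receptor, was highest at 100 h, at 16079 ± 39.5 against 5293 ± 1060 at 80 h and 8606 ± 245 at 120 h, and both differences from 100 h passed the test (adjusted p = 8.4e-05 and 0.0084).

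**Figure D1:**
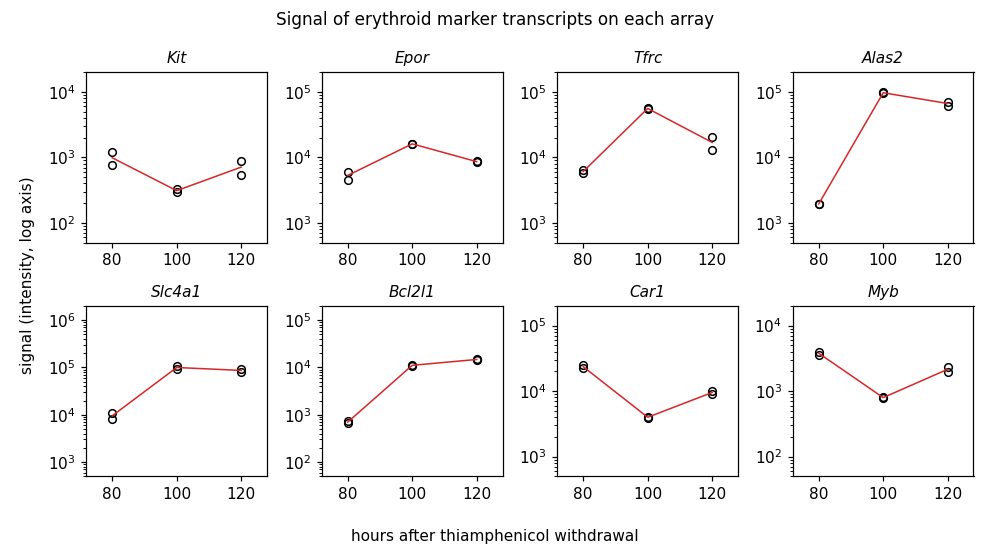
Signal of 8 erythroid transcripts on each array (points, log axis, intensity) against hours after thiamphenicol withdrawal, with a line through the mean of the 2 arrays of each stage. Tfrc and Alas2 were highest at 100 h, and Kit, Car1 and Myb had their lowest means there.

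The comparison of 100 h with 80 h asks what changed as the cells gained Ter119. Xpo7, a nuclear export receptor, went from 600 ± 114 to 46439 ± 543 (log2 fold change 6.05 ± 0.14, adjusted p = 4.5e-07), and Alas2, the first enzyme of erythroid heme synthesis, from 1942 ± 34.3 to 97015 ± 2091 (5.57 ± 0.11, adjusted p = 3.3e-07). Tbcel, Tent5c, Fhdc1, Sowaha, Rsad2, Gch1, Bpgm and Reln completed the 10 largest increases, with log2 fold changes of 5.18, 5.15, 5.11, 5.07, 4.87, 4.86, 4.80 and 4.75. All 11 measured genes of the red cell membrane list rose, with a median log2 fold change of 2.23, among them Slc4a1 (the band 3 anion exchanger, 3.39 ± 0.16), Epb42 (3.58 ± 0.16), Dmtn (2.99 ± 0.13) and Rhd (2.40 ± 0.11); adjusted over the list alone the count was also 11. Camera with a preset correlation of 0.01 called the list higher (adjusted p = 2.2e-06, but adjusted p = 0.18 with an estimated correlation).

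Of 11 heme synthesis genes, 10 rose, including Ppox (2.48 ± 0.15), Urod (2.42 ± 0.11) and Slc25a39 (2.42 ± 0.11), and Tmem14c fell (-1.04); the counts were the same adjusted over the list alone (camera adjusted p = 0.00014; adjusted p = 0.19 with an estimated correlation). Among 5 globin genes 4 rose, also adjusted over the list alone, at Hba-a1 from 57320 ± 5068 to 143767 ± 2802 and at Hbb-b2 from 16716 ± 1187 to 80161 ± 926 (list adjusted p = 0.015; adjusted p = 0.18 with an estimated correlation). Globin genes are close copies that 1 probe set can share, and the brightest probe sets can be compressed, so their values are uncertain. The list of erythroid enzymes and chaperones was called higher, with 7 genes up and 1 down (8 and 1 adjusted over the list alone; list adjusted p = 0.007, adjusted p = 0.18 with an estimated correlation). Bpgm, which makes the regulator of oxygen affinity 2,3-bisphosphoglycerate, rose by 4.80 ± 0.15 and Hagh by 1.97 ± 0.12, while the carbonic anhydrase gene Car1 fell from 23604 ± 1497 to 3985 ± 74.9 and Car2 rose by 0.77 ± 0.12.

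Erythroid transcription factors were called higher as a list, with 11 of 17 up and 2 down (11 and 3 adjusted over the list alone; camera adjusted p = 0.0079, adjusted p = 0.27 with an estimated correlation). Klf3 rose by 2.52 ± 0.13, Nfe2 by 2.44 ± 0.16, Foxo3 by 2.30 ± 0.13, Sox6 by 1.85 ± 0.19 and Gata1 by 1.23 ± 0.13. A second Gata1 probe set did not pass (0.46 ± 0.19, adjusted p = 0.07). Klf1 (0.24 ± 0.12, adjusted p = 0.13) and Gata2 (0.32 ± 0.18, adjusted p = 0.16) did not pass. The transcription factor genes Myb (-2.11 ± 0.16) and Myc (-1.04 ± 0.29) fell. Tfrc, the transferrin receptor through which cells take up iron, went from 6079 ± 445 to 55790 ± 1678. Of transcripts downstream of Epo receptor signalling, Bcl2l1, which encodes the survival factor Bcl-xL, rose from 698 ± 61.0 to 11098 ± 209 and Pim1 from 4644 ± 581 to 23061 ± 1851, and Cish did not pass (0.38 ± 0.28, adjusted p = 0.28). The list of EPO receptor signalling as a whole was not called, with 5 of 20 up and 2 down by both adjustments (camera adjusted p = 0.33). Ptpn6 (-1.93 ± 0.26) and Shc1 (-1.19 ± 0.21) were the members that fell.

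Of 30 ribosome biogenesis genes 28 fell and none rose, also adjusted over the list alone, with a median log2 fold change of -1.87. Nhp2 (-3.84 ± 0.16), Gar1 (-3.66 ± 0.15) and Rrs1 (-3.33 ± 0.28) fell, and Npm1, encoding nucleophosmin, went from 24044 ± 523 to 2438 ± 198. Camera called the ribosome biogenesis list lower (adjusted p = 1.7e-09; adjusted p = 0.17 with an estimated correlation). Proteasome genes fell in 30 of 36 cases with none up (median -1.39), led by Psma3 (-2.79 ± 0.15), and the count was 30 adjusted over the list alone (camera adjusted p = 9.6e-08; adjusted p = 0.17 with an estimated correlation). Heat shock and chaperone genes fell in 21 of 28 cases and rose in 2, the same adjusted over the list alone (median -1.84, camera adjusted p = 9.2e-07; adjusted p = 0.17 with an estimated correlation). The inducible Hsp70 genes Hspa1a and Hspa1b, close copies of each other, had log2 fold changes of -4.14 ± 0.25 and -3.83 ± 0.17, and the constitutive Hspa8 fell by 3.15 ± 0.13.

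Oxidative phosphorylation genes fell in 44 of 64 cases and rose in 5 (44 and 8 adjusted over the list alone; median -1.09, camera adjusted p = 3.8e-06, adjusted p = 0.18 with an estimated correlation), among them Ndufb5 (-2.40 ± 0.13) and Uqcrc2 (-2.30 ± 0.16). Glycolysis genes fell in 9 of 12 cases with none up, also adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.17 with an estimated correlation); the lactate dehydrogenase gene Ldha went from 14539 ± 1318 to 696 ± 73.9 and hexokinase Hk1 fell by 2.89 ± 0.22. Translation factor and tRNA synthetase genes fell in 37 of 55 cases and rose in 3, the same adjusted over the list alone (adjusted p = 4.4e-05; adjusted p = 0.17 with an estimated correlation). Eif6 fell by 2.67 ± 0.29. Ribosomal protein genes fell in 19 of 28 cases and rose in 2, the same adjusted over the list alone (adjusted p = 0.0037; adjusted p = 0.29 with an estimated correlation). Rpl10a fell by 1.89 ± 0.11. The remaining largest decreases were Samm50, Mrpl12, Cad, Mrpl35 and C1qtnf12, with log2 fold changes of -4.37, -4.06, -3.98, -3.59 and -3.57.

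Cell cycle genes moved in both directions. DNA replication genes fell in 20 of 38 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.0037; adjusted p = 0.17 with an estimated correlation). Pold2 (-2.79 ± 0.19) and Mcm7 (-1.54 ± 0.19) fell. Mitosis genes rose in 22 of 35 cases and fell in 4 (23 and 4 adjusted over the list alone; adjusted p = 0.0026, adjusted p = 0.17 with an estimated correlation), with Mki67 from 7956 ± 1078 to 38519 ± 3079. The list of G1 and arrest regulators was called higher with 12 of 25 up and 4 down, the same adjusted over the list alone (adjusted p = 0.043; adjusted p = 0.19 with an estimated correlation). Its leaders were the kinase inhibitor Cdkn2d (4.57 ± 0.35) and the Myc antagonist Mxd1 (4.14 ± 0.29), followed by Mxi1 (2.30 ± 0.18) and Ccng2 (2.23 ± 0.22).

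Markers of other cell types also differed. The macrophage list was called higher at 100 h with 10 of 17 up and 1 down (12 and 1 adjusted over the list alone; adjusted p = 0.005, adjusted p = 0.17 with an estimated correlation), led by Ctsb (2.42 ± 0.12), a lysosomal protease that many cells make. C1qb rose by 1.13 ± 0.21. Of 11 granulocyte markers 6 fell and 2 rose (6 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.15). S100a8 stood at 54.2% and Ngp at 31.4% of their 80 h means. The B cell, T cell, megakaryocyte, mast cell and stromal lists were not called. The 3' to 5' signal ratio of the actin controls, a sign of RNA quality, was 2.22 ± 0.0350 at 80 h, 1.49 ± 0.269 at 100 h and 1.77 ± 0.192 at 120 h (n = 2 each). The same ratio of the Gapdh controls was 1.37 ± 0.145 at 80 h, 0.812 ± 0.00392 at 100 h and 1.72 ± 0.201 at 120 h. Across all 7150 probe sets, 3938 were called at 100 h against 80 h, 1871 higher and 2067 lower, and the median log2 fold change was 0.11. Without moderation of the variance 2606 were called.

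**Figure D2:**
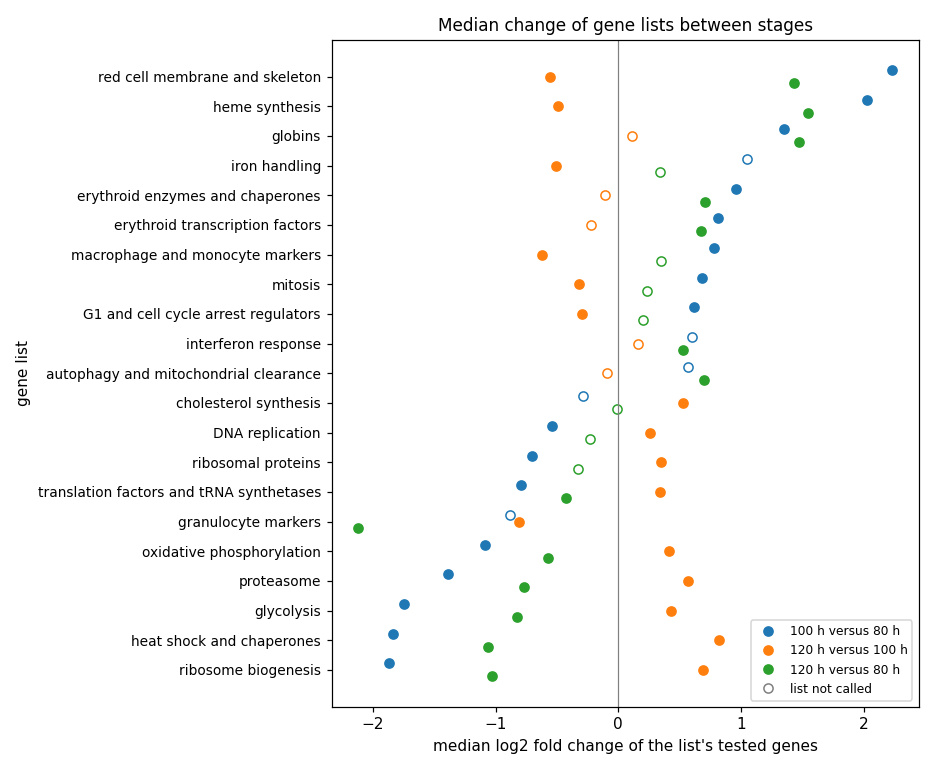
Median log2 fold change of the tested genes of each list called in at least 1 comparison (rows), for the 3 comparisons (colours); filled points are lists called by camera with a preset correlation and open points are lists that were not. Ribosome biogenesis had a median of -1.87 at 100 h against 80 h and 0.69 at 120 h against 100 h.

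The comparison of 120 h with 100 h asks what changed as the cells lost Epo receptor and scatter. The 3' to 5' signal ratio of the Gapdh controls was higher at 120 h (1.72 ± 0.201) than at 100 h (0.812 ± 0.00392). Cad, which starts pyrimidine synthesis, rose from 150 ± 13.1 to 1722 ± 287 (2.83 ± 0.19, adjusted p = 0.00039), Rcc2 from 424 ± 123 to 3544 ± 37.7 and Ldha from 696 ± 73.9 to 4331 ± 520. Pdrg1, Parp1, Mrpl12, Uck2, Uqcc2, Trip6 and Mrpl35 followed with log2 fold changes of 2.29, 2.27, 2.24, 2.22, 2.20, 2.19 and 2.15. Ribosome biogenesis genes rose in 11 of 30 cases with none down (14 adjusted over the list alone; camera adjusted p = 1.1e-08, adjusted p = 0.18 with an estimated correlation). Npm1 rose by 1.89 ± 0.12, Ncl by 1.81 ± 0.13 and Bop1 by 2.10 ± 0.29. Proteasome genes rose in 17 of 36 cases with none down (20 adjusted over the list alone; adjusted p = 1.6e-06, adjusted p = 0.18 with an estimated correlation). Psmb9, also a member of the interferon response list, rose by 2.11 ± 0.27. Oxidative phosphorylation genes rose in 20 of 64 cases and fell in 1 (25 and 1 adjusted over the list alone; adjusted p = 2.6e-06, adjusted p = 0.18 with an estimated correlation). Ndufb5 rose by 1.39 ± 0.13. Heat shock and chaperone genes rose in 15 of 28 cases and fell in 3 (16 and 3 adjusted over the list alone; adjusted p = 0.0022, adjusted p = 0.18 with an estimated correlation). Hspa8 rose by 1.83 ± 0.13.

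At 120 h 11 of 55 translation genes, 8 of 28 ribosomal protein genes, 10 of 38 DNA replication genes, 6 of 12 glycolysis genes and 2 of 7 cholesterol synthesis genes also rose, or 16, 15, 13, 6 and 3 adjusted over the list alone. Of these lists only DNA replication also had genes lower, 2 in number by both adjustments. Camera called the lists higher with adjusted p of 0.00021, 0.00046, 0.0062, 0.0097 and 0.022, and with an estimated correlation the adjusted p was 0.18, 0.24, 0.18, 0.18 and 0.23. Rps18 rose by 1.08 ± 0.10, Rrm1 by 0.85 ± 0.12, Pfkm by 1.32 ± 0.20 and Fdps by 1.02 ± 0.22. Myb rose by 1.32 ± 0.16 and Car1 by 1.24 ± 0.12.

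Genes of iron uptake, heme synthesis and the red cell membrane fell. Tfrc fell to 16895 ± 5440 (-1.75 ± 0.20, adjusted p = 0.0025), a second Tfrc probe set fell by 3.63 ± 0.18, and the iron transporter gene Slc11a2 fell by 1.43 ± 0.20; 2 of 5 iron handling genes fell and none rose, or 3 and none adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.23 with an estimated correlation). Heme synthesis genes fell in 5 of 11 cases with none up (6 down and 1 up adjusted over the list alone; adjusted p = 0.0037, adjusted p = 0.27 with an estimated correlation). Abcb10 (-1.06 ± 0.12), Uros (-0.89 ± 0.12) and Alas2 (-0.55 ± 0.11) fell. Urod, counted among these 5 (-0.76 ± 0.11), showed no fall with its probe sets averaged. Red cell membrane genes fell in 7 of 11 cases with none up (9 adjusted over the list alone; adjusted p = 9.7e-05, adjusted p = 0.23 with an estimated correlation). Aqp1 fell by 0.88 ± 0.14. Slc4a1 (-0.21 ± 0.16, adjusted p = 0.46), Car2 (-0.13 ± 0.12, adjusted p = 0.53), Pim1 (-0.33 ± 0.16, adjusted p = 0.24; a second probe set fell by 0.87) and Bcl2l1 (0.41 ± 0.12, adjusted p = 0.066) did not pass, nor did any of the 5 globin genes. Gata1 fell by 0.53 ± 0.13, but its second probe set did not pass (-0.13 ± 0.19, adjusted p = 0.71).

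Mitosis genes fell in 9 of 35 cases and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 2.8e-05, adjusted p = 0.18 with an estimated correlation). Bub1 (-1.36 ± 0.18), Prc1 (-1.24 ± 0.11) and Mki67 (-1.02 ± 0.13) fell. The list of G1 and arrest regulators was called lower with 4 of 25 down and 1 up (5 and 2 adjusted over the list alone; adjusted p = 0.048, adjusted p = 0.23 with an estimated correlation). Mxd1 (-2.15 ± 0.29) and Cdkn2d (-1.38 ± 0.35) fell. The kinesin gene Kifc1 fell by 2.74 ± 0.37, although its 100 h arrays differed widely, at 3859 ± 2267. Scd1 (-2.18 ± 0.16), Slc2a4 (-2.27 ± 0.30) and H3c8 (-2.18 ± 0.48) fell.

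Among the steepest decreases at 120 h were genes of granulocytes. Ngp, a neutrophil granule protein gene, fell from 4286 ± 79.7 to 221 ± 30.4 (-3.76 ± 0.18), S100a8 from 12223 ± 346 to 1450 ± 0.928 (-2.99 ± 0.11), and S100a9 (-2.67 ± 0.15) and Ltf (-2.17 ± 0.23) fell as well. Granulocyte markers fell in 6 of 11 cases with none up, also adjusted over the list alone (camera adjusted p = 3.8e-06; adjusted p = 0.18 with an estimated correlation). Macrophage markers fell in 5 of 17 cases with none up, also adjusted over the list alone (adjusted p = 0.00015; adjusted p = 0.18 with an estimated correlation). Lyz2 (-2.24 ± 0.22) and C1qa (-1.79 ± 0.34) fell. Anxa1 (-2.59 ± 0.24) and the class II gene H2-Ea (-2.40 ± 0.36) fell. Of the 7150 probe sets, 981 were called, 633 higher and 348 lower. Without the filter on dim probe sets 660 were called, 438 of them higher. Without 1 of the 100 h arrays the count was 515 (replicate 1) or 505 (replicate 2), and without 1 of the 120 h arrays 372 (replicate 1) or 480 (replicate 2). It was 596 with a variance prior that did not follow the signal and 73 without moderation.

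**Figure D3:**
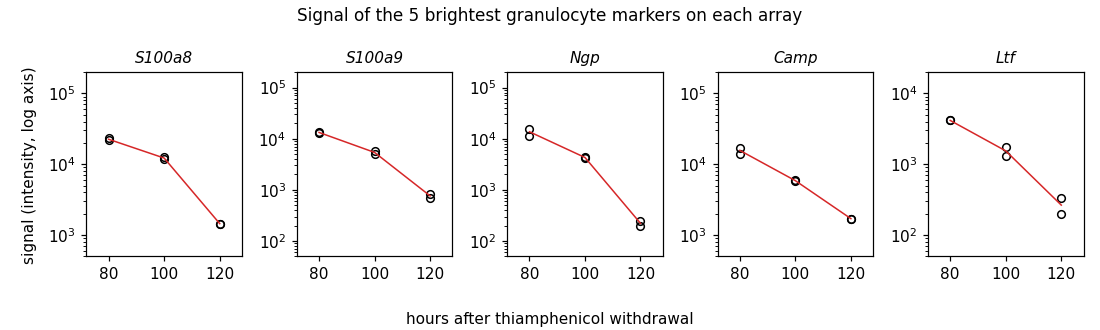
Signal (intensity, log axis) of the 5 granulocyte markers with the highest 80 h means, on each array (points) with a line through the mean of the 2 arrays of each stage. S100a8 had means of 22534, 12223 and 1450 at 80, 100 and 120 h.

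The comparison of 120 h with 80 h spans the whole interval. Xpo7 was higher by 5.99 ± 0.14, Tent5c by 5.36 ± 0.14, Sowaha by 5.03 ± 0.23, Tbcel by 5.02 ± 0.16, Alas2 by 5.02 ± 0.11 and Bcl2l1 by 4.21 ± 0.12, and Rsad2, Bpgm, Fhdc1 and Gch1 completed the 10 largest increases. All 11 red cell membrane genes were higher (adjusted p = 5.4e-07; adjusted p = 0.19 with an estimated correlation), as were 9 of 11 heme synthesis genes with 1 lower (adjusted p = 0.0001; adjusted p = 0.23 with an estimated correlation) and 4 of 5 globin genes (adjusted p = 0.0025; adjusted p = 0.19 with an estimated correlation). Adjusted over the list alone these counts were 11, 10 with 1 lower, and 4. Slc4a1 was higher by 3.18 ± 0.16 and Hbb-b2 by 2.29 ± 0.11. Erythroid enzymes (8 of 10 up and 1 down by both adjustments; adjusted p = 0.0026, adjusted p = 0.19 with an estimated correlation) and erythroid transcription factors (11 of 17 up and 1 down, or 11 and 3 adjusted over the list alone; adjusted p = 0.003, adjusted p = 0.23 with an estimated correlation) were also called higher. Klf3 was higher by 2.17 ± 0.13, Foxo3 by 2.08 ± 0.13, Tfrc by 1.42 ± 0.20, Epor by 0.70 ± 0.15, Gata1 by 0.70 ± 0.13, Pim1 by 1.96 ± 0.16 and Car2 by 0.64 ± 0.12. Klf1, Gata2 and Cish did not pass (adjusted p = 0.33, 0.063 and 0.43). The second Gata1 probe set did not pass either (0.33 ± 0.19, adjusted p = 0.2).

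Autophagy genes were called higher as a list, with 7 of 16 up and none down by both adjustments (camera adjusted p = 0.0099; adjusted p = 0.19 with an estimated correlation), including Ulk1 (1.84 ± 0.15), Gabarapl2 (1.63 ± 0.12) and Map1lc3a (1.28 ± 0.21). Interferon response genes were higher in 8 of 16 cases and lower in 2, also adjusted over the list alone (adjusted p = 0.028; adjusted p = 0.23 with an estimated correlation). Rsad2 went from 606 ± 110 to 22471 ± 1172, Isg15 was higher by 3.25 ± 0.13, Ifit1 by 2.77 ± 0.34 and Igtp by 2.47 ± 0.16, and Irf1 was lower (-2.29).

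Several lists called lower at 100 h than at 80 h were also called lower at 120 h than at 80 h. Ribosome biogenesis genes were lower in 22 of 30 cases (24 adjusted over the list alone; adjusted p = 3.2e-08, adjusted p = 0.19 with an estimated correlation), heat shock and chaperone genes in 22 of 28 with 1 higher (25 and 1 adjusted over the list alone; adjusted p = 7.6e-08, adjusted p = 0.19 with an estimated correlation) and proteasome genes in 22 of 36 (23 adjusted over the list alone; adjusted p = 2.1e-06, adjusted p = 0.19 with an estimated correlation). Gar1 (-2.34 ± 0.15), Hspa1a (-4.35 ± 0.25), Hspa1b (-3.04 ± 0.17) and Psma3 (-2.25 ± 0.15) fell. Oxidative phosphorylation (30 of 64 lower and 4 higher, or 34 and 6 adjusted over the list alone; adjusted p = 0.0003, adjusted p = 0.23 with an estimated correlation), translation (24 of 55 lower and 2 higher by both adjustments; adjusted p = 0.0013, adjusted p = 0.19 with an estimated correlation) and glycolysis (9 of 12 lower by both adjustments; adjusted p = 0.0026, adjusted p = 0.19 with an estimated correlation) were called lower too. The lists of ribosomal proteins (13 of 28 lower and 2 higher, or 14 and 2 adjusted over the list alone; adjusted p = 0.058), DNA replication (8 of 38 lower and 2 higher, or 7 and 2 adjusted over the list alone; adjusted p = 0.058) and cholesterol synthesis (2 of 7 lower and none higher by both adjustments; adjusted p = 0.57) were not called. Hk1 (-2.57 ± 0.22), Uqcrc2 (-1.44 ± 0.16), Car1 (-1.30 ± 0.12), Myb (-0.79 ± 0.16), Myc (-0.89 ± 0.29) and Gtf2h1 (-3.05 ± 0.28) fell.

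Granulocyte markers were lower in 7 of 11 cases and higher in 2 by both adjustments (camera adjusted p = 0.0029; adjusted p = 0.23 with an estimated correlation). Ngp (-5.39 ± 0.18), S100a9 (-3.95 ± 0.15), S100a8 (-3.86 ± 0.11), Ltf (-3.55 ± 0.23) and Camp (-3.12 ± 0.13) fell. Csf3r (0.88 ± 0.19) and Lcn2 (0.62 ± 0.17) were higher. A second Lcn2 probe set fell by 3.43, so the direction of Lcn2 is unsettled. Lyz2 (-3.02 ± 0.22) and Anxa1 (-3.41 ± 0.24) fell too. The macrophage and B cell lists were not called (adjusted p = 0.19 and 0.081). In all 2672 probe sets were called, 1270 higher and 1402 lower. Without 1 of the 80 h arrays the count was 1606 (replicate 1) or 1480 (replicate 2), and without replicate 2 of 120 h it was 1526. It was 1127 without moderation.

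A contrast of 100 h with the mean of the other stages asked which transcripts turned there. With both neighbouring differences also called, 284 probe sets peaked and 610 had a trough at 100 h. With each gene represented by its brightest probe set, the largest peaks were Reln (31.7 ± 8.36, 3584 ± 348 and 937 ± 2.54 at 80, 100 and 120 h), Mxd1, Alas2, Kifc1 and Cdkn2d, and the deepest troughs were Cad, Ldha, Rcc2, Mrpl12 and Mrpl35. The second Tfrc probe set stood at 772 ± 210, 20522 ± 215 and 1557 ± 17.9. With the offset added, its log2 difference of 100 h from the mean of the other stages was 4.11 ± 0.15, against 3.29 ± 0.18 for Reln. The 80 h mean of Reln (31.7) lay below the offset, so the difference of Reln is understated. Which of these probe sets peaked by more is therefore not settled. By contrast, 14 probe sets were called higher and 50 lower at 120 h than at both other stages. The turn count of 894 fell to 478 and 468 without replicate 1 or 2 of 100 h, and to 338 and 428 without replicate 1 or 2 of 120 h. The peaks among these turns were also fewer than 284, but a stage left with 1 array gives less power to call a turn. The loss therefore does not show that the peaks depend on a particular array. Without the filter on dim probe sets 179 of 603 turns were peaks. The turn count was 547 with a variance prior that did not follow the signal and 67 without moderation.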

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

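All tests named in this part were chosen after the patterns were seen, except that of the second neutrophil list, which was written before its values were seen. Of the control probe sets, which no comparison uses, 3 are given here. Each differed between 80 h and 100 h and lay above the highest signal (505) of the bacterial Dap, Lys, Phe, Thr and Trp controls in the stage where it was higher. The 5' Gapdh control gave 27124 ± 292 at 80 h and 7146 ± 239 at 100 h, a ratio of 3.80 (6.41 for the 3' part and 3.44 for the middle part). The 5' transferrin receptor control gave 7548 ± 318 at 100 h against 280 ± 38.8 at 80 h, a ratio of 26.9 (18.9 for the 3' part and 17.4 for the middle part). The 3' pyruvate carboxylase control gave 2147 ± 95.5 at 100 h against 632 ± 11.9 at 80 h, a ratio of 3.40 (4.83 for the 5' part, and 13.5 and 3.24 for the middle parts, of which the latter stayed below 505). At 80 h the 5' and middle transferrin receptor parts (280 and 363) lay below 505. So did the 5' and middle pyruvate carboxylase parts (203, 85.4 and 123). The size of the ratios taken over these means is therefore uncertain.

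The first pattern is that 120 h lay between 80 h and 100 h for 85.1% of the 3938 probe sets called between those stages, a share that choosing them by their 80 h and 100 h values may raise. A scaling factor per array was argued against (a first test, by counts of turns under other scalings, moved the values too little to decide), since it would shift all probe sets the same way, while the median log2 fold change from 100 h to 120 h was -0.30 (SE 0.012 over probe sets) for those called higher at 100 h than at 80 h and 0.53 (SE 0.015) for those called lower, with the same signs where 1 replicate of 100 h selected them and the other measured them. A fixed mixture of cells like those at 80 h and 100 h would imply 1 share of 80 h signal, and a first test, the spread of implied shares (26.0 against a limit of 26.3 percentage points), decided nothing. In a second test, chosen after that, the median share was 13.0 points higher for probe sets risen at least 4-fold than for those fallen (9.96 and 17.8 in the replicates). Its SE of 2.43 treats probe sets of the same arrays as independent. A signal too low on the 120 h arrays would raise the first share and lower the second. The test therefore argues against a mixture only if these arrays are scaled correctly. A mixture together with 1 scaling factor per array was not tested directly. It would give nearly the same implied share for all probe sets risen at least 4-fold. Their quartiles were 22.7% and 60.0%, while the 120 h replicates differed by a median of 9.86 points. For these 232 probe sets the spread argues against that combination. Among the 403 fallen the spread was narrower, with quartiles of 17.0% and 35.7% and a replicate difference of 7.81 points. An exchange of the 100 h and 120 h labels cannot be told apart from the order given, because Epor was lower at 120 h (-0.89) while Kit pointed the other way (0.95, not called), and a program of stage II stays open and untested.

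The second pattern is the fall of ribosome biogenesis, chaperone and proteasome transcripts at 100 h. Dilution by abundant erythroid transcripts would lower all other genes as much. Their median log2 fold change was 0.11 (SE 0.0199) against -1.87, -1.84 and -1.39 for the 3 lists. Scaling to a common level largely sets the median of the other genes, so its value alone cannot show whether dilution took place. A factor per array leaves the gap between the lists and the other genes nearly unchanged. Equal dilution of all genes would not give this gap. RNA degradation at 100 h would raise the 3' to 5' ratio of the controls there, but the actin ratio was 1.49 ± 0.269 against 2.22 ± 0.0350 at 80 h, and the Gapdh ratio 0.812 ± 0.00392 against 1.37 ± 0.145. A change of the cells with stage stays open as a hypothesis.

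The third pattern is the fall of granulocyte transcripts, with Ngp at 1.62% and S100a8 at 6.43% of their 80 h means by 120 h. From 80 h to 120 h, the median of the macrophage list (0.35, SE 0.327) lay 2.47 (SE 0.894) above that of the granulocyte list (-2.12, SE 0.832). That of the B cell list (-0.51, SE 0.216) lay 1.61 (SE 0.860) above it. The macrophage markers went both ways, with 6 of 17 higher and 3 lower, among them Lyz2 (-3.02 ± 0.22). They include genes that many cells make, such as Ctsb. A lower share of all cells other than erythroid cells is therefore not decided for this interval. Between 100 h and 120 h it cannot be told apart from a fall of granulocyte transcripts alone, as the macrophage list fell too (medians -0.62 and -0.81, 0.20 apart, SE 0.564) and the B cell list (-0.01) lay 0.80 (SE 0.546) above the granulocyte list. A candidate explanation is granulocyte RNA, which bead purification should remove, that decreased between the preparations, but of a second list of 26 neutrophil genes 12 were tested, and 1 (Pglyrp1) was called lower and 1 (Tspo) higher at 120 h than at 80 h, with a median of -0.34 and a list that limma's camera did not call. This tie met the bound written beforehand against the explanation, and reading it as deciding nothing was chosen after it was seen: 8 of the 12 had 80 h means below 1000, and the other 4, Selplg (0.02), Slpi (0.04), Hp (-0.24) and Tspo (0.88), none called lower, had 120 h means of 1408 to 20008, a signal that would hide a small granulocyte share, so the explanation, which this list did not support, cannot be told apart from lower expression in the erythroid cells.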

How the results depend on the processing

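The fit with only the 4 arrays of the 2 stages compared and the counts without the granulocyte, macrophage, B cell and T cell genes were chosen after seeing the data. Total counts stayed within 1.5 times those reported under no scaling, which moves almost nothing here, quantile normalization, median scaling, other offsets, a floor, other filters, averaged probe sets, no family probe sets and, for the stage pairs alone, both added settings. Without the filter on dim probe sets, though, the peaks numbered 179 against 284, and 438 of 660 calls for 120 h against 100 h were higher. A variance prior that ignores the signal gave 596 calls for 120 h against 100 h and 547 turns, and the cause was not tested. An ordinary test without moderation, which has fewer degrees of freedom by construction, gave 2606, 73, 1127, 1750 and 67 calls for 100 h against 80 h, 120 h against 100 h, 120 h against 80 h, any stage and turns. Leaving out 1 array gave 2922 to 3928, 372 to 780, 1480 to 2672, 2407 to 3442 and 338 to 693 in that order, with the lone array assumed to vary like the others. Of 93 list tests 46 were called, 42 to 48 without 1 array, 66 with fry and 0 with camera and estimated correlations (22 at an unadjusted p under 0.05). The replicate numbers did not pair the arrays, since replicate differences of different stages correlated at 0.0773, 0.000316 and 0.0173. A replicate block gave 3920, 911, 2602, 3537 and 834 calls and 45 lists. Of 270 gene and comparison pairs named by the rule, 76 lost their call without moderation, 9 to 21 without 1 array and at most 12 of those tested under any other setting (237 pairs were tested with the filter at the 75th percentile, 233 without family probe sets, 242 without the genes of the other cell lists and 260 with 4 arrays), and 3 turned sign somewhere, all at 120 h against 100 h, and the cause was not tested. Urod (-0.76) was 0.00 with its probe sets averaged. Cish (-0.09, not called) was 0.11 without replicate 1 of 100 h and 0.03 without replicate 2 of 120 h, in a range of -0.29 to 0.11 without 1 array. Ireb2 (0.06, not called) was -0.18 without replicate 2 of 100 h, in a range of -0.18 to 0.30. Dim signals near the offset limit what can be called.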

Other observations

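The lists of both paragraphs below were chosen after the leading genes had been seen, and each test without the leading genes was written before its value was seen.

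Genes of the mitochondrial ribosome fell together at 100 h. Of 55 measured, 48 were lower and 1 higher than at 80 h, with a median log2 fold change of -1.71, and at 120 h 25 were higher and 1 lower than at 100 h. Mrpl21 fell from 2098 to 175 and Mrps25 from 1133 to 65.1, while Mrps18a rose by 0.61 ± 0.13. Because Mrpl12 and Mrpl35 had drawn attention to the list, it was tested without them: 46 of the other 53 genes were lower and camera gave p = 1.9e-13, or p = 0.0055 with an estimated correlation, consistent with a shift of the whole list. These p-values are not adjusted over the 31 lists set beforehand.

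Of 17 purine and pyrimidine synthesis genes 11 fell and 3 rose at 100 h, with a median log2 fold change of -1.30 (camera p = 0.01, or adjusted p = 0.07 with an estimated correlation), and at 120 h 5 were higher and none lower than at 100 h (p = 0.0027, or adjusted p = 0.048 with an estimated correlation). Cad and Uck2 had drawn attention to the list, so these p-values include the genes that prompted it. The adjusted values cover only the lists of this part, not the 31 set beforehand. They cannot be compared with the adjusted p of those 31 lists, of which the smallest with an estimated correlation was 0.18 at 120 h against 100 h. At 100 h without this pair 9 of the other 15 were lower and 3 higher, with a median of -1.03, and camera did not call the list at the threshold of 0.05 (p = 0.064, or p = 0.14 with an estimated correlation). Cad (log2 fold change -3.98 ± 0.19) and Uck2 (-3.42) fell, Adsl went from 2282 to 310, and Nme1 (1.38), Uck1 (1.14) and Dhodh (0.65) rose.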
